A study of Mus musculus with 2 samples.

How the data were processed

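Epididymal white adipose tissue of male mice was profiled on Affymetrix mouse arrays. Per the labels and design text, total RNA was isolated with TRIzol, the RNA of 5 animals per genotype was pooled, and each pool was labelled with biotin and hybridised. There is 1 array of the wild-type pool and 1 of the PPARβ/δ knockout pool. The design text names the 430 2.0 array, whereas the probe annotation supplied with the values is that of the smaller 430A array, and the table analysed holds 22690 probe sets. The deposited values are probe set intensities made by the authors with GCRMA 2.20, per the submitters' processing notes; GCRMA corrects background from probe sequence, normalises quantiles between arrays and summarises the probes of a set. GCRMA gives log2 values by default, but the deposited values run from 1.91 to 36322 and are therefore on a linear scale. Which arrays were normalised together is not given in the sources used here. The quartiles were close between arrays (10.7 and 106 in the wild-type pool, 10.4 and 113 in the knockout pool). Quantile normalisation assumes that most genes do not differ, and background correction with GCRMA pulls dim probe sets towards a common low value, which enlarges folds of genes near background. The design had been written for log2 values, so log2 of each intensity was taken first and nothing else was changed.

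Genes were named from the annotation of the array, updated by Entrez identifier to the symbols of GRCm38.p6 gene records. Of the probe sets, 20393 named 1 gene (20364 of them matched by identifier, 29 kept the annotation's name), 691 named several and 1606 none. The last 2 kinds were left out of the gene comparison. There were 64 Affymetrix control probe sets, and those naming 1 gene were treated like any other probe set, among them the one that represents Gapdh. A probe set was kept when its log2 value was at least 5 (an intensity of 32) on at least 1 array. This floor was reached by 42.0% of probe sets on the wild-type array and 43.1% on the knockout array. It stands in for detection calls, which were not used here. Each gene was represented by its kept probe set with the highest mean over both arrays, which left 6533 genes. Differences are log2 knockout minus log2 wild type; where the dimmer value was below the floor, the fold is given as "at least", with that value set to the floor.

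With 1 array per genotype no p-value, SE or SD between samples exists, and none is given. Genes at least 2-fold different were counted, on the values as measured unless stated. For 31 gene lists, fixed with all other choices before the data were examined unless stated, the median difference of kept members was set against the medians of 10000 random lists of the same size drawn from 20 bins of mean expression. A list of at least 5 kept members was said to stand apart when its median lay below the 2.5th or above the 97.5th percentile. This describes these 2 arrays and does not test genotypes. Of the 344 genes kept from the lists, 11 belong to several. The named genes are Ppard, the 8 genes with the largest and the 8 with the smallest difference among those whose kept probe sets all point the same way (RIKEN, EST and predicted genes passed over), and the kept members of each list at its extremes, 1 at each end or 2 for lists that stood apart. Every other gene named in the report or in the observations after it was chosen after its values were seen, among them Angptl4, Pdk4, Fasn, Scd1, Acacb, Mlxipl, Nnt, Glo1 and the genes below the floor.

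The scripts were tested on simulated data. For these 2 pools and 6533 genes, lists shifted by -0.8 stood apart in 82% of cases with 8 genes, 97% with 15 and 100% with 30, and unshifted lists in 5%, 4% and 3%. Each simulated gene took the difference of a random gene of its own expression bin, from the bins used for the random lists. The low rate for unshifted lists was therefore built in. Simulated lists held unrelated genes, so this is not a false-call rate for the fixed lists, whose members may vary together. In a simulation of 2-fold counts over 6148 kept genes with noise of SD 0.3, all 50 genes raised by 2 on the log2 scale were counted, 39 of the 50 raised by 1.3, 42 of 50 lowered by 2, 35 of 50 lowered by 1.3, and 13 unchanged genes. The SD of 0.3 was set by hand and not estimated from these arrays, where differences of kept genes had quartiles of -0.50 and 0.42. The 13 therefore do not measure how many of the counted genes differ by noise alone.

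Control probe sets gave the following values. The ratio of the 3' to the 5' probe set, which rises with RNA degradation, was 2.30 in the wild-type and 2.48 in the knockout pool for actin, and 0.80 and 0.91 for Gapdh. The spiked control cre (3' probe set) was at 9700 in the wild-type and 9812 in the knockout pool and bioD at 2316 and 2403. The spiked control dap was at 549 and 339, a log2 difference of -0.70. A further probe set of cre differed by 0.13 and a further one of dap by -0.85. Alternatives were the floor, the probe set per gene, the probe sets used, the scaling, an offset of 32 added to the intensity before log2, the size of change counted and the matching of random lists. Computations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, with matplotlib 3.10.9 for figures.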

Results

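Gene expression in epididymal white adipose tissue, the fat pad that lies against the epididymis and testis of male mice, was compared between mice lacking the nuclear receptor PPARβ/δ (gene Ppard) and wild-type mice, all on standard chow. RNA of 5 animals per genotype was pooled and each pool was hybridised to 1 Affymetrix array, so the comparison rests on 1 wild-type and 1 knockout value per gene. No spread between replicates could be computed, no test between genotypes was possible, and differences are reported as measured in these 2 arrays. The number of arrays limits the precision. The spiked controls and the agreement of different probe sets of 1 gene show part of the technical error only. They do not measure differences between animals or in dissection. Of the spiked controls, cre differed by 0.02 and dap by -0.70 on the log2 scale, and a further probe set of each by 0.13 and -0.85. Among 2137 genes with several probe sets above the intensity floor, the SD of the log2 difference between probe sets of 1 gene had a median of 0.25 and a 90th percentile of 0.75, and all probe sets pointed the same way for 1557 genes (72.9%). Both labels give male mice, the wild-type animals being 12 to 16 weeks old and the knockout animals 12 weeks old. The sources differ on strain, since the design text calls the controls littermates of a mixed Sv129/C57BL/6 background and the label of the wild-type sample gives 129S1/SvJae. Strain may therefore differ between the pools.

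The log2 intensities of the 2 arrays correlated with r = 0.944 over all 22690 probe sets, a correlation across probe sets, which are not independent replicates. Over the 6533 genes kept for the comparison r was lower, 0.822. Median intensity was 22.3 in the wild-type pool and 23.0 in the knockout pool. Of 12394 genes represented, 6533 reached an intensity of 32 on at least 1 array. Of these, 893 (13.7%) were at least 2-fold higher in the knockout pool and 597 (9.14%) at least 2-fold lower. The larger differences were mostly on the higher side: as measured, 179 genes were 16-fold or more higher and 1 gene 16-fold or more lower. With values below the floor set to the floor, these counts were 120 and 0, and the 2-fold counts were 743 higher and 522 lower. Of the 893 higher genes, 462 were below the floor in the wild-type pool and 431 at or above it.

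The targeted gene, Ppard, was below the intensity floor in both pools. The intensity of its single probe set was 6.58 in the wild-type pool and 6.27 in the knockout pool, against a floor of 32, a log2 difference of -0.07. Which part of the transcript this probe set covers relative to the disrupted part is not given in the sources used here, so Ppard expression gives no check of the genotype labels. The male marker Eif2s3y was at 508 in the wild-type pool and 567 in the knockout pool, and the female marker Xist was below the floor on both arrays, as were the other male markers measured, Kdm5d and Uty.

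Transcripts of testis germ cells were higher in the knockout pool and had the largest median difference of the 31 lists. All 18 germ cell markers were at least 2-fold higher there, with a median log2 difference of 4.60, about 24.3-fold, and quartiles of 3.92 and 5.43. With the 4 wild-type values below the floor set to the floor, the median was 4.52. None of 10000 random gene lists matched on mean expression had a median as high. Prm1, a protamine that packs sperm DNA, was at 1193 in the wild-type and 10833 in the knockout pool. Akap4, a protein of the sperm tail, was at 63.4 and 5047, and Sycp3, part of the meiotic synaptonemal complex, at 179 and 854. The testis kinase Tssk2 was at 12.3, below the floor, and 926, at least 28.9-fold higher in the knockout pool.

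Of the 8 named genes with the largest differences, 7 were below the floor in the wild-type pool. Spz1, a spermatogenic transcription factor, was at least 85.4-fold higher and Iqcf3 at least 91.1-fold. Gk2, a testis glycerol kinase, was at least 82.4-fold higher and Cetn1, a centrin of germ cells, at least 41.9-fold. The lower of the probe sets of Iqcf3 differed by 5.68 on the log2 scale, and that of Cetn1 by 2.58. Tsga8 was at least 40.8-fold higher, Pgam2 at least 34.8-fold, and Catsperz, a subunit of the sperm calcium channel, at least 33.9-fold. Meig1, which is needed for spermiogenesis, was at 45.2 in the wild-type pool and 3947 in the knockout pool, an 87.3-fold difference. These bounds set wild-type values below the floor to an intensity of 32.

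Epididymis markers were present in both pools and slightly higher in the knockout pool, with median log2 intensities of 11.95 in the wild-type and 12.58 in the knockout pool. Of 13 measured markers 12 were higher there, 1 of them at least 2-fold, and the median log2 difference was 0.33. A median as high was found in 31 of the 10000 matched random lists, but the median lay within the central 95% of unmatched random lists, and it was 0.18 with no floor. The secretory proteins Cuzd1 (9657 in the wild-type and 9440 in the knockout pool) and Gpx5 (7698 and 8173) differed little, and the difference of Cuzd1, -0.03, turned positive when differences were centred on their median or the trend with intensity was removed. The β-defensins Defb1 and Defb2 were higher, by 1.57 and 0.98 on the log2 scale, and averaging the probe sets of Defb1 gave 0.94. The seminal vesicle genes Svs2, Svs3a, Svs4, Svs5 and Sva, placed in the same list, were below the floor on both arrays.

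**Figure D1:**
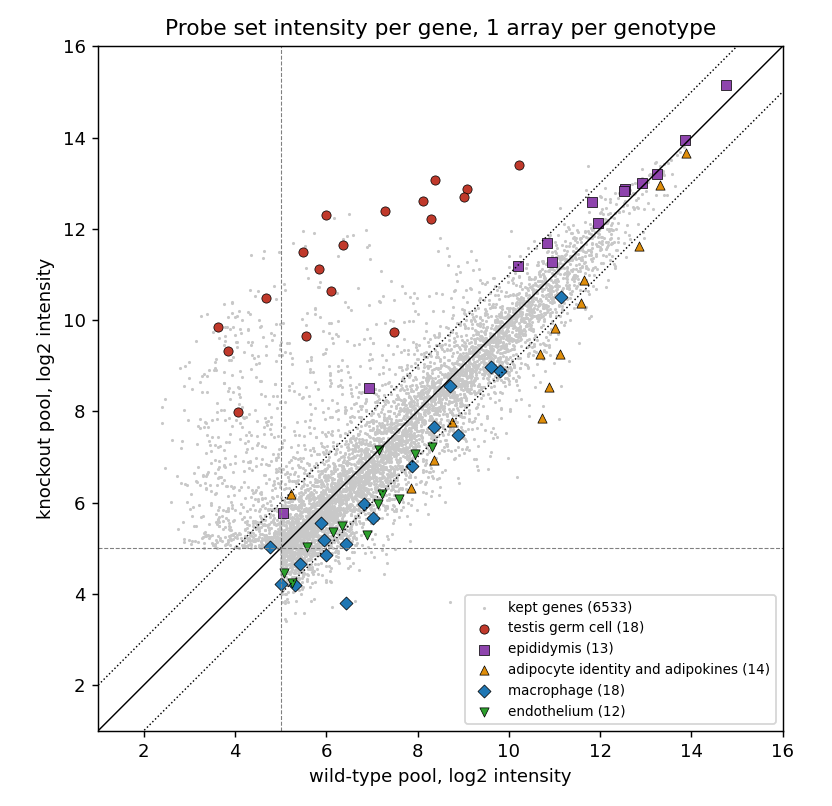
Log2 intensity of each of the 6533 kept genes in the wild-type pool (x axis) and the knockout pool (y axis), 1 array each; the solid line marks equal values, dotted lines a 2-fold difference, and dashed lines the floor. The 18 germ cell markers lie above the upper dotted line, 12 of the 13 epididymis markers lie within the dotted lines, Defb1 being the exception, and 13 of 14 adipocyte genes lie below the solid line, 9 of them below the lower dotted line.

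Adipocyte genes were lower in the knockout pool. Of 14 measured adipocyte identity and adipokine genes, 13 were lower, 9 of them at least 2-fold, with a median log2 difference of -1.21 (quartiles -1.51 and -0.83). No random list had a median as low. Lep, the satiety hormone leptin, was at 1698 in the wild-type and 233 in the knockout pool, a 7.30-fold difference. Pparg, the nuclear receptor that directs adipocyte differentiation, was 5.12-fold lower. The fatty acid carrier Fabp4, in contrast, was at 15004 and 13018, a log2 difference of -0.20, though its probe sets ranged from -1.88 to -0.10 and averaged -0.70. The probe sets of Aqp7, a glycerol channel, disagreed in direction: the one that represents the gene differed by 0.96, whereas the mean over its probe sets was -0.53. The same knockout pool held the germ cell transcripts at a median difference of 4.60 and the epididymis transcripts at 0.33.

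Genes of triglyceride turnover and of fatty acid oxidation were lower as groups; the difference between the groups was not tested. Of 13 triglyceride synthesis and lipolysis genes 11 were lower, with a median log2 difference of -0.97, matched or undercut by 1 of 10000 random lists. G0s2, an inhibitor of adipose triglyceride lipase, was 3.79-fold lower and Lpin1, a phosphatidate phosphatase, 2.85-fold lower, whereas Agpat3 was 1.98-fold higher. Abhd5, the coactivator of that lipase, differed by 0.24 at the probe set that represents it and by -0.56 over the mean of its probe sets. Of 25 genes of fatty acid oxidation and PPAR targets 20 were lower, with a median of -0.59, matched or undercut by 3 random lists, but only Decr1 (5.35-fold) and Vnn1 (2.13-fold) were lower by 2-fold or more. The log2 difference of Vnn1 ranged from -1.09 to -0.85 over the alternatives, so it did not always reach 2-fold. The established PPAR target Angptl4 was at 1239 and 1024, and Pdk4 at 72.1 and 37.6. Germ cell markers were higher in this pool by a median of 4.60. Fabp3, the heart-type fatty acid carrier, was at 25.4, below the floor, in the wild-type pool and at 114 in the knockout pool, and Acot1 was 1.54-fold higher.

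De novo lipogenesis genes did not stand apart from random lists, with a median of -0.12 over 18 genes. Fasn, the fatty acid synthase, was at 4051 and 3771, and Scd1 at 11459 and 11083. Within this list 3 genes were lower by 2-fold or more. Pnpla3, a lipase regulated by feeding, was at 1161 in the wild-type and 94.6 in the knockout pool, 12.3-fold lower. Acacb, an acetyl-CoA carboxylase, was 4.95-fold lower and Mlxipl, a carbohydrate-responsive transcription factor, 2.52-fold lower. Acss2 was 2.41-fold higher, with a log2 difference of 0.82 at the lower of its probe sets. Cholesterol synthesis genes (13 genes, median 0.05) ranged from Sc5d, 4.58-fold lower, to Fdft1, squalene synthase, 2.87-fold higher. Of 32 respiratory chain genes 28 were lower, none by 2-fold, and their median of -0.26 lay at the 10.5th percentile of random lists. The extremes were Sdhb, at -0.81, and Ndufv2, at 0.34. Of 10 brown and beige adipocyte genes with a probe set, 9, including Ucp1, were below the floor on both arrays, and Ppargc1a was at 35.6 and 28.1.

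Markers of the other cells of the fat pad were lower along with the adipocyte genes. Of 18 macrophage markers 17 were lower, with a median log2 difference of -0.83, or -0.75 with values below the floor set to the floor. Cd163, a haemoglobin scavenger receptor, was at least 2.68-fold lower and Laptm5 2.65-fold lower, whereas Ctss differed by -0.17 and Gpnmb was at 27.2, below the floor, in the wild-type pool and at 32.6 in the knockout pool. Of 12 endothelial markers 11 were lower (median -0.95, or -0.87 with dim values at the floor), led by Sox18 (3.01-fold) and Vwf, von Willebrand factor (2.87-fold), with Cdh5 at -0.53 and Cldn5 at 0.01. Of 10 preadipocyte and fibroblast markers 7 were lower (median -0.72, or -0.33 with values below the floor set to the floor). Among them, Cd34 was 2.23-fold lower and Ebf2 at least 1.07-fold, whereas Dpp4 and Zfp423 were 1.60-fold and 1.24-fold higher. The macrophage and endothelial medians were matched or undercut by 1 and 4 of 10000 random lists. The preadipocyte median was matched by 46, and this list no longer stood apart with a floor of log2 6 or without probe sets of shared sequence. Smooth muscle markers differed in the other direction without standing apart (8 genes, median 0.33), from Mustn1, 2.22-fold lower, to Myh11, smooth muscle myosin, 2.05-fold higher. Mesothelial markers (7 genes, median -0.01) ranged from Gpm6a, 2.81-fold lower, to Krt8, 1.55-fold higher. Their median depended on the setting: it was 0.07 when differences were centred, 0.42 with a floor of log2 6, -0.20 with no floor and -0.78 without probe sets of shared sequence. These cell markers were measured in the pool whose germ cell markers were higher by a median of 4.60.

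Extracellular matrix genes and genes of inflammation and the acute phase were lower in the knockout pool. Of 29 matrix genes 28 were lower, 12 at least 2-fold (median -0.82). Col5a2, a fibrillar collagen, was 4.78-fold lower and the gelatinase Mmp2 at least 3.97-fold lower, with Bgn at -0.24 (-0.81 at the lowest of its probe sets) and Ccn2 at 0.12. Of 11 inflammation and acute phase genes 10 were lower, 7 at least 2-fold (median -1.17, or -0.43 with no floor). The chemokine Ccl8 was at least 2.79-fold lower and Saa3, a serum amyloid, at least 2.00-fold, with Nfkbia at -0.30 (-0.58 over the mean of its probe sets) and Lcn2, lipocalin 2, at 0.46. No random list had a median as low as either list, and both were measured beside the germ cell transcripts, higher by a median of 4.60. Tnf, Il6, Il1b and Ccl2 were below the floor on both arrays. Of 4 measured interferon response genes all were lower, from the immunoproteasome subunit Psmb8 (4.29-fold) to Ifi27l2a (1.65-fold); 4 genes were too few for the comparison with random lists.

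Insulin signalling and glucose metabolism genes were lower on balance (17 of 22, median -0.63, matched or undercut by 1 random list). Pik3r1, the regulatory subunit of phosphoinositide 3-kinase, was 4.11-fold lower and the insulin-responsive glucose transporter Slc2a4 2.88-fold lower. In the same list hexokinase Hk1 was 8.45-fold higher and the phosphofructokinase Pfkp at least 2.91-fold higher, in the pool with germ cell markers higher by a median of 4.60. All 13 measured nuclear receptor and cofactor genes were lower (median -0.62, matched or undercut by 90 random lists); after Pparg, the repressor Bcl6 was lowest at 2.43-fold, and Rarg differed least, at 36.6 in the wild-type pool and 31.8, below the floor, in the knockout pool. Circadian clock genes stood apart as lower (9 genes, median -0.71, 124 random lists) but split widely. The clock output factors Dbp and Tef were 6.04-fold and 3.78-fold lower, the deubiquitinase Usp2 was 8.53-fold higher (with a log2 difference of 1.46 at the lower of its probe sets), and Cry1 at least 1.93-fold higher.

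Heat shock and unfolded protein response genes were higher on balance, 15 of 19 with a median of 0.24, which 124 matched random lists reached; the median lay within the central 95% of unmatched lists. Germ cell markers (median 4.60) and epididymis markers (median 0.33) were higher in the same pool. The endoplasmic reticulum proteins Sdf2l1 and Creld2 were 2.76-fold and 2.49-fold higher, and Hspb1 and Xbp1 1.59-fold and 1.57-fold lower. Immediate early genes, which respond to tissue handling, did not stand apart (11 genes, median -0.45). Among them, Dusp1 was 2.74-fold lower and Egr2 1.80-fold higher.

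The other genes at the lowest end were of mixed function. Serpina1b, an α1-antitrypsin gene, has near-identical paralogs, so its value is uncertain as to the gene. It was at 419 in the wild-type pool and 14.0 in the knockout pool, below the floor, at least 13.1-fold lower. Tmem45b was 9.65-fold lower, Mest, an imprinted gene linked to fat cell size, 8.12-fold, and Id3, an inhibitor of helix-loop-helix factors, 7.03-fold. Alas2, the erythroid haem synthesis enzyme, was at least 4.83-fold lower and Hal, histidine ammonia-lyase, at least 3.09-fold. Hbb-b2 was at least 1.61-fold lower. Of lymphocyte markers, Ighm was 4.18-fold and Jchain 1.31-fold lower, while the 15 T and NK cell markers and the 12 mast cell and granulocyte markers with a probe set were all below the floor. The muscle marker Myl1 was 2.26-fold lower, the other 16 of 17 skeletal muscle genes with a probe set being below the floor, and the Schwann cell markers Pmp22 and Mal were 2.72-fold lower and 1.92-fold higher.

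Neighbours of Ppard on chromosome 17 did not stand apart. Over 20 measured neighbours the median difference was -0.10, with 9 higher and 11 lower. It was positive with the intensity trend removed (0.01) and with a floor of log2 6 (0.04) or log2 4. The extremes were Pi16, at least 1.13-fold lower, and Tcp11, 38.5-fold higher, which is also in the germ cell list. Of the genes known to differ between 129 and C57BL/6 strains, Ifi202b was 2.18-fold lower and Nnt, the nicotinamide nucleotide transhydrogenase, was at 497 and 244. Glo1 was at 807 and 1241. Wdfy1 was 3.14-fold higher, but its probe sets ranged from -0.13 to 1.65.

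**Figure D2:**
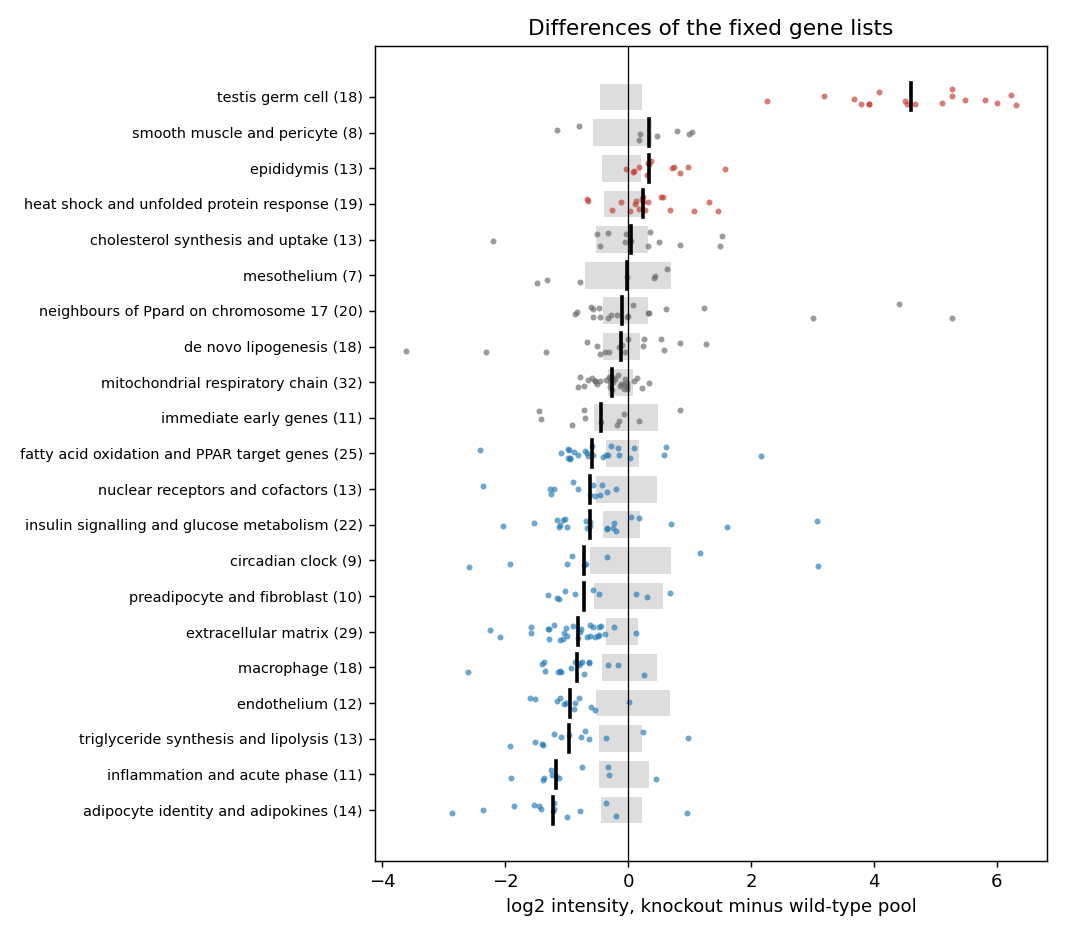
Log2 difference, knockout minus wild-type pool (x axis), of each measured gene in the 21 fixed lists with at least 5 measured members (number in parentheses); each point is a gene, the black bar the list median, and the grey band the central 95% of medians of matched random lists. Points are red for the 3 lists that stood apart as higher, blue for the 11 that stood apart as lower and grey for the other 7; the germ cell list has a median of 4.60.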

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

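Probe sets that name no single gene entered none of the comparisons of genes or gene lists. Of 860 such probe sets above the floor, 75 were at least 2-fold higher in the knockout pool than in the control pool, 15 of them at least 16-fold as measured, and 66 were at least 2-fold lower. Among the 6533 kept genes, 893 were at least 2-fold higher, 179 of them at least 16-fold, and 597 at least 2-fold lower. Each of these shares was larger than that among the probe sets naming no single gene. The units differ, however: each gene was represented by its kept probe set with the highest mean, whereas every probe set naming no single gene was counted. Those probe sets were flagged for lying outside the main measurement and not for differing more often.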

How the results depend on the processing

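The 893 higher and 597 lower genes stayed within 1.5 times these counts under another floor, another choice of probe sets, centring or removal of the intensity trend. An offset of 32 left 649 higher and 344 lower genes, the lower count falling outside that range. Counting 1.5-fold differences gave 1355 higher and 1390 lower genes, and counting 3-fold differences gave 599 higher and 148 lower. In alternatives chosen after seeing the data, values set to the floor gave 743 higher and 522 lower genes, and 431 higher genes remained when the floor had to be reached in the wild-type pool, which by construction leaves out genes dim there. The offset shrinks every log2 difference, most for dim genes, so by construction it cannot add calls. Why the count of lower genes fell by a larger share than that of higher genes was not tested. The number of gene lists standing apart was 14 of 21 and ranged from 12 to 15. Over all alternatives, 185 of 189 list results and 695 of 719 named-gene results kept their side of the threshold, 180 and 691 of them with the same sign. No called value changed sign; the signs that turned were those of Ppard, Abhd5, Aqp7, Cuzd1 and the mesothelium and chromosome 17 lists, none of them called. The lists that lost their side were the preadipocyte list (-0.57 with a floor of log2 6, -0.53 without probe sets of shared sequence) and the epididymis and heat shock lists against unmatched random lists. The germ cell median stayed between 4.18 and 4.72 and the adipocyte median between -1.21 and -1.11, while the inflammation median ranged from -1.23 to -0.43. Ppard has 1 probe set, so its value could not be compared between probe sets. With 1 array per genotype no replicate could be left out. No paired analysis was possible because each genotype has 1 pool. Signal over background limits the genes below the floor on both arrays, Ppard among them, whose differences are uncertain one by one.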

Other observations

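As measured, 58 genes were at least 4-fold lower in the knockout pool, 53 with dim values set to the floor. A few of them outside the fixed lists are given here, picked after their values were seen and not tested as a group. Hsd11b1, which regenerates active glucocorticoid, was at 2249 in the wild-type and 374 in the knockout pool, and H6pd, which supplies its cofactor, was 5.94-fold lower. Nnmt, nicotinamide N-methyltransferase, was 5.83-fold lower, the matrix protease Adamts5 6.25-fold, the natriuretic peptide clearance receptor Npr3 4.10-fold and the amino acid transporter Slc7a10 5.60-fold. In the same pool germ cell markers were higher by a median of 4.60, and macrophage, endothelial and preadipocyte markers had a median of -0.87.

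The tests that follow on another tissue, the share of fat pad RNA, the intensity trend and the X chromosome, those over all listed testis markers and all uses of floored values were chosen after the result was seen; the other tests on testis cell types were written before.

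The first pattern is the germ cell transcripts in the knockout pool, for which RNA of testis tissue is a candidate explanation. The tests written before used markers that reached the floor and decide nothing, because the floor was met only in the knockout pool by 8 of 9 spermatogonia and spermatocyte markers (median 3.31, lower quartile 1.81, which was to rule out sperm of the epididymal lumen as the only source) and by 3 of 6 Leydig and Sertoli markers (median 2.08). Over all 16 spermatogonia and spermatocyte markers with a probe set and no floor, all 16 were higher, Syce2 at 38.0 and 575 among them, and the median was 1.59, above every random list but short of the 2 asked for, while 7 were below the floor in both pools, such as Stra8, and the median was 0.11 with dim values at the floor. Of all 16 Leydig and Sertoli markers 15 were higher with a median of 0.88, above every random list, which goes with testis RNA and against sperm alone, from Cyp17a1 (44.0 and 312) and Cst9 (at least 6.73-fold) to Sox9 (0.05), while 10 were below the floor in both pools and the median was 0.00 with dim values at the floor. RNA of another tissue altogether is argued against by the adipocyte genes, whose median was -1.21 where -4 or less was needed, with a lower quartile of -1.51, while testis tissue, sperm alone (as most of these markers lie near or below the floor) and an effect of the knockout itself, untested with 1 pool per genotype, stay open.

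The second pattern is the lower adipocyte genes, and a smaller share of fat pad RNA in the knockout pool would lower all its cell types alike: 35 of 40 macrophage, endothelial and preadipocyte markers were lower, with a median of -0.87 (1.82-fold), and the adipocyte median differed from theirs by -0.35 (95% bootstrap interval over genes -0.69 to 0.12, which describes these genes and not animals). That interval holds 0, as this explanation needs, and so does the one with dim values at the floor, -0.94 to 0.01, only just. Both are wide and also hold a larger fall of the adipocyte genes, down to -0.69 and -0.94, so they do not show an equal fall. Outside the test, 6 of 8 smooth muscle markers were higher (median 0.33, as for the epididymis markers). Whether the smooth muscle transcripts came from the fat pad was not tested. The mesothelium median ranged from -0.78 to 0.42 over the alternatives and decides nothing. Lep (7.30-fold) and Fabp4 (1.15-fold, with probe sets from -1.88 to -0.10 on the log2 scale) differed unequally. Also outside the test, the 18 de novo lipogenesis genes did not stand apart (12 lower and 6 higher, median -0.12). A smaller share alone would lower these transcripts too, as far as they came from the fat pad. Their source was not tested. A trend of the differences with intensity is argued against as the whole cause, since the median was -1.11 with the trend removed. The genotype, the strain named in the labels, the age range and the dissection of the pad all differ between the 2 arrays or may do so, and stay open as untested.

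The third pattern is a low number of X-linked genes among those at least 2-fold higher in the knockout pool: 12 of 893 (1.34%), against 3.08% of all kept genes, where matched random sets held 17 to 35 in their central 95%. Silencing of the X chromosome in meiotic germ cells is a candidate explanation. It cannot be decided here: genes below the floor in the wild-type pool, predicted to be the more depleted, held 1.52% and the others 1.16%, and the genes at least 16-fold higher held 5 of 179.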
